A study of Mus musculus with 12 samples.

How the data were processed

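Polyadenylated RNA of the basolateral amygdala (BLA) and the central amygdala (CeA) was sequenced in male wild-type mice of 2 inbred strains, C57BL/6 (B6) and 129S1/SvImJ (S1). Mice were naive, fear-conditioned (FC) or taken through fear extinction (Ext), per the labels. The series' design text names the medial part of the central amygdala (CEm), while the sample labels say CeA, and the labels' word is used here. Each of the 12 combinations of strain, region and condition was 1 library, so no group had a replicate. The labels do not say how many mice went into a library, nor whether the BLA and CeA libraries of a strain and condition came from the same mice. RNA was extracted with RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols.

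The authors deposited 1 pair of tables for the 8 naive and conditioned libraries and another for the 4 extinction libraries, each with values per gene and per transcript. StringTie was used, per the submitters' processing notes, and the tables name the mm10 build. The aligner, the software versions and whether the counting used strand are not given in the sources used here. The deposited read counts are whole numbers per transcript and per gene, not normalized. FPKM values per gene were deposited beside them, scaled by the authors for transcript length and library size. The remaining deposited measure was transcript length in bases, per the file headers. In the gene table, 1 count column carried a name that did not say which naive B6 library it held, and it was matched to no sample. Gene counts were therefore computed as sums of the deposited transcript counts over the 36779 transcripts of each table, which gave 24531 genes. In the other 11 libraries these sums equalled the deposited gene counts in all but 73 to 95 genes, and the totals differed by at most 0.0511%. No pair of libraries was identical.

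Total counts were 42224899 to 61695302 per library. A floor of 3 counts corresponded to 0.0486 to 0.071 CPM (counts scaled to library size). Where every library of a group was at 0, a fold change is given as a lower bound against 3 counts over that group, and such bounds cover counting error alone. Genes sharing reads with near-identical copies, overlapping genes and antisense genes are named as uncertain.

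Gene counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test after trimmed mean of M values (TMM) scaling and filterByExpr. P-values were adjusted by the method of Benjamini and Hochberg, and the threshold was an adjusted p of 0.05. The strain (S1 minus B6), region (BLA minus CeA) and conditioning (FC minus naive) effects came from an additive model of the 8 naive and conditioned libraries, with 4 residual degrees of freedom. Interactions of strain with conditioning and of strain with region each added a term and left 3. The extinction libraries were fitted alone, with strain and region as terms and 1 residual degree of freedom. Extinction was not compared with the naive or conditioned state directly, because it was deposited in a separate table. The change of the strain gap was tested across all 12 libraries, as the gap after extinction minus the mean gap in naive and conditioned mice, with 5 residual degrees of freedom. Since each group was 1 library, every p-value measures spread around the additive model between these libraries, not between mice. Standard errors (SE) were derived from the log2 fold change and the F statistic. Adjusted p without another name is edgeR's.

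Genes were named by a rule. For each comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean CPM of at least 1 and the same sign in every matched pair of libraries. Predicted genes were left out. Where no gene passed, the 3 smallest p-values in each direction were taken and given as not past the threshold. Members of the fixed lists could be named as well.

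The 26 lists covered phospholipase A2, eicosanoid and endocannabinoid, GABA transmission, glutamate transmission, immediate early, glucocorticoid-responsive, neuropeptide, monoamine receptor, extracellular matrix, complement with antigen presentation and interferon, respiratory chain and ribosomal protein genes. They also held markers of BLA excitatory neurons, CeA, striatum, intercalated cells, interneurons, astrocytes, microglia, oligodendrocytes, their precursors, endothelial and mural cells, ependyma with choroid plexus, and blood, besides sex-linked genes and strain reference genes. Lists of at least 5 tested genes were tested with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Counts of members were also adjusted over the list alone. The comparisons, lists, naming rule and first group of other settings were fixed before the data were examined. The lists of other neuronal and other microglial genes used in the closing section were written later.

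Those other settings were relative log expression factors, DESeq2 1.42.0, no filter on low counts, a CPM filter, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, leaving out each library, a matched-pair block, all 12 libraries in one model, and summed BLA and CeA counts. Removal of each library's trend on transcript length (loess offsets, span 0.5) and fits of each region alone were chosen after seeing the data.

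Each test was checked on counts simulated from the real libraries' means and sizes, with 200 genes changed. The changed genes had a mean CPM of at least 1, and dispersions followed the trend on mean level. Spread particular to single genes was not simulated, so recovery in the real data may be lower. At 2-fold, edgeR recovered 95% of changed genes for the strain effect, 96% for region, 99% for conditioning, 38% for strain by conditioning, 58% for strain by region, 87% for strain after extinction, 87% for region after extinction and 58% for the change of the strain gap. At 1.5-fold these shares were 77%, 79%, 82%, 10%, 5%, 43%, 43% and 14%. Intervals over list members used 10000 resamples at the 95% level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.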

Results

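The data were gene read counts from 12 libraries, 1 for each combination of strain (B6 or S1), region (BLA or CeA) and condition (naive, FC or Ext). S1 mice are the strain with impaired fear extinction in this study, and the series asked which genes relate to that impairment. The total count of the naive libraries was 54925204 in B6 BLA, 47888634 in B6 CeA, 45628847 in S1 BLA and 42224899 in S1 CeA. After conditioning the totals were 57206071, 45117479, 47913126 and 52631712 in the same order, and after extinction 59091734, 50013722, 61695302 and 55869170. Between 17147 and 17630 genes were detected per library.

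Pla2g4e, which encodes the epsilon form of cytosolic phospholipase A2, separated the strains in every pair of libraries. It lies on chromosome 2 at 120166412 to 120245335 (mm10; Gene_ID 329502). In naive and conditioned mice it was 7.41-fold higher in S1 (log2 fold change 2.89 ± 0.28 SE, adjusted p = 0.00056, 4 of 4 matched pairs). Naive B6 mice had 6.85 CPM in BLA and 4.75 CPM in CeA, against 28.7 and 52.4 CPM in naive S1 mice. After extinction it was 8.05-fold higher in S1 (log2 fold change 3.01 ± 0.15, adjusted p = 0.01, 2 of 2 pairs), with 27.8 CPM in S1 BLA and 50.4 CPM in S1 CeA.

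The strain gap in Pla2g4e was smaller in BLA than in CeA, an interaction of −1.41 ± 0.21 that did not pass over all genes (adjusted p = 0.17) but passed when adjusted over the list alone (adjusted p = 0.0038). Its conditioning effect was −0.15 ± 0.26 (adjusted p = 1), and its strain gap after extinction differed from the earlier gap by 0.15 ± 0.45 (adjusted p = 0.97). Among the 17 phospholipase A2 genes tested before extinction, 3 were higher and 2 lower in S1, and the same numbers passed when adjusted over the list alone. Besides Pla2g4e, the higher ones were Pla2g6, a calcium-independent phospholipase (0.43 ± 0.08, adjusted p = 0.0078), and Pafah2, an intracellular platelet-activating factor hydrolase (0.34 ± 0.08, adjusted p = 0.021). Lower in S1 were Pla2g7, the secreted hydrolase of platelet-activating factor (−0.75 ± 0.06, adjusted p = 0.00027), and Pla2g12a, a secreted phospholipase (−0.57 ± 0.11, adjusted p = 0.012). Pafah2 no longer passed without B6 naive CeA (adjusted p = 0.06), B6 FC BLA (0.067), B6 FC CeA (0.089), S1 naive CeA (0.08), S1 FC BLA (0.075) or S1 FC CeA (0.058). The other 4 passed without any 1 library.

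After extinction, Pla2g4e and Pla2g7 (−0.61 ± 0.07, adjusted p = 0.045) passed over all genes, and 2 higher and 2 lower members passed when adjusted over the list alone, with Pla2g6 at 0.51 and Pla2g12a at −0.48. As a set the family showed no shift between strains before extinction (median −0.06, mean 0.04, camera adjusted p = 0.98) or after it (median −0.08, camera direction up, adjusted p = 0.85). For conditioning 0 members passed by edgeR over both regions, and the list median was −0.06 (camera adjusted p = 0.72). In the BLA libraries fitted alone, Pafah1b1, a subunit of a platelet-activating factor hydrolase, fell by −1.63 (adjusted p = 0.00063), a gene and a fit both chosen after the values were seen. Its change was −1.66 in B6 BLA and −1.58 in S1 BLA against −0.08 and −0.09 in CeA, and −0.86 ± 0.28 over both regions (adjusted p = 1). After extinction Pafah1b1 had 715.6 CPM in B6 BLA and 224.9 CPM in S1 BLA.

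**Figure D1:**
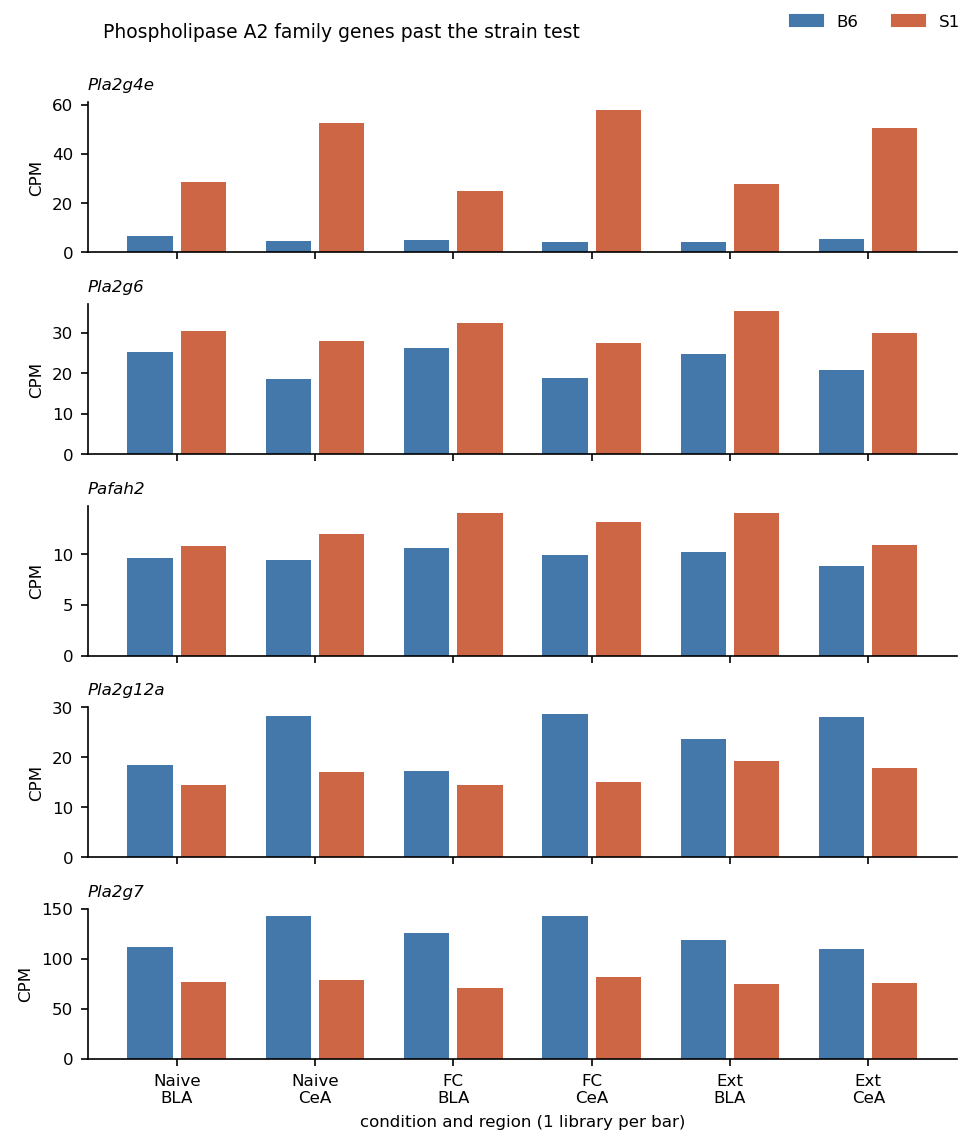
CPM per library of the 5 phospholipase A2 family genes past the strain test in naive and conditioned mice; each bar is 1 library, blue for B6 and orange for S1. Pla2g4e lies between 4.09 and 6.85 CPM in the B6 libraries and between 24.8 and 58 CPM in the S1 libraries.

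The largest strain differences before extinction lay in genes with low counts in either B6 or S1. Loss of S1 reads at sites that differ from the mm10 reference was not measured. Low S1 counts are uncertain in that respect. Pttg1, which encodes the mitotic protein securin, was 61.7-fold lower in S1 (−5.95 ± 0.19, adjusted p = 3.2e-06), lies on chromosome 11 at 43420248 to 43426248, and was lower in 4 of 4 pairs. Lower in S1 as well were Rec8, a meiotic cohesin (−5.57 ± 0.36), Bub1b, a mitotic checkpoint kinase (−4.74 ± 0.46), Bfsp2, a lens filament protein (−4.76 ± 0.2), Sugct, a mitochondrial CoA transferase (−4.58 ± 0.49), Oscar, an immune receptor of myeloid cells (−4.34 ± 0.33), Eps8l1 (−3.91 ± 0.24) and Myo7a, an unconventional myosin (−3.74 ± 0.38). Gdpd3, a lysophospholipase D, was 24.7-fold higher in S1 (4.62 ± 0.14, adjusted p = 2.4e-06, 4 of 4 pairs; chromosome 7, 126766414 to 126775645). Higher too were Sla2, a Src-like adaptor (4.81 ± 0.54), Hcar1, a lactate receptor (4.46 ± 0.69), the serine protease gene Prss41 (4.28 ± 0.42), Myh6, a cardiac myosin heavy chain (4.25 ± 0.83), and the transcript AA465934 (4.08 ± 0.15).

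Klk1b22 was at 0 in all 4 B6 libraries and at least 217-fold higher in S1, Mettl7a2 was at least 136-fold higher, and Olfr287 was at 0 in S1 and at least 150-fold lower. These 3 belong to families of near-identical genes, as does Vmn2r29 (−4.35 ± 0.26). Mir686 (6.65 ± 0.22) is a very short gene and Arhgap33os (5.41 ± 0.38) is antisense to another, so read assignment is uncertain for all 6.

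In total 3712 of 16274 genes (22.8%) differed between strains in naive and conditioned mice, 2021 higher and 1691 lower in S1, and 623 of them by at least 2-fold. The median log2 fold change ran with transcript length, from −0.162 among genes with the shortest transcripts (up to 1756 bases) to 0.172 among those with the longest (from 4177 bases) (Spearman correlation across genes 0.401). The ribosomal RNA precursor Rn45s took 1.209% and 1.706% of counts in S1 CeA against 0.34% and 0.867% in B6 CeA (naive and FC). In BLA it took 0.59% and 0.154% in S1 against 0.372% and 0.332% in B6. Leaving out 1 library gave 1489 genes without B6 FC CeA, 1716 without B6 naive CeA, 1716 without B6 FC BLA, 1801 without S1 naive CeA, 2242 without S1 FC CeA, 2336 without S1 FC BLA and 2415 without S1 naive BLA. Without B6 naive BLA the count rose to 5227. Of the 3712 calls 54.4% were higher in S1, against 40.1% with limma on log2(FPKM + 1), which called 1327 higher and 1982 lower.

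Of 27 genes of GABA transmission tested before extinction, 9 were higher in S1 and 0 lower, or 10 and 1 when adjusted over the list alone. Gad2, which synthesizes GABA, was higher by 0.25 ± 0.05 (adjusted p = 0.015), Slc32a1, the vesicular GABA transporter, by 0.24, the receptor subunits Gabra2 and Gabrb1 by 0.31 and 0.6, and Nlgn2, an adhesion protein of inhibitory synapses, by 0.29. The list median was 0.11 (camera adjusted p = 0.027; adjusted p = 0.61 with an estimated correlation), and 0.03 once the trend on transcript length was removed. The count of higher genes was 0 without B6 naive CeA or S1 naive CeA, 1 without B6 FC BLA, 2 without B6 FC CeA, S1 FC BLA or S1 FC CeA, 7 without S1 naive BLA and 14 without B6 naive BLA. List medians in these fits were 0.1 to 0.16. Of the genes named, Gad2 did not pass without B6 naive CeA (adjusted p = 0.057), B6 FC BLA (0.056), S1 naive CeA (0.063) or S1 FC BLA (0.056). The other 4 each failed in 4 to 6 of the 8 such fits.

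Glutamate transmission genes had 11 of 30 higher and 1 lower, or 13 and 1 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.011; adjusted p = 0.61 with an estimated correlation) and 0.09 without the length trend. The count of higher genes was 0 without B6 FC CeA, 2 without B6 naive CeA or B6 FC BLA, 4 without S1 naive CeA, 5 without S1 naive BLA, S1 FC BLA or S1 FC CeA and 14 without B6 naive BLA. List medians in these fits were 0.13 to 0.24. Among them were the kinase Camk2a (0.42), the NMDA receptor subunits Grin2a (1.01 ± 0.26) and Grin2b (1.02 ± 0.3), and Grm3 (−0.2). Camk2a did not pass without B6 FC BLA (adjusted p = 0.05) or B6 FC CeA (0.068). The other 3 each failed in 5 to 7 of the 8 fits. After extinction 0 genes of the GABA or glutamate list passed by edgeR over all genes, and the medians were 0.03 for GABA (camera adjusted p = 0.31) and 0.13 for glutamate transmission (camera adjusted p = 0.059). The fit after extinction had 1 residual degree of freedom and called 1.64% of all genes, against 22.8% before. Its count of 0 therefore does not show that a strain difference was lost.

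Complement, antigen presentation and interferon genes were lower in S1. Of 22 tested before extinction, 0 were higher and 12 lower, or 14 lower when adjusted over the list alone. C1qb, a chain of the first complement component, was 1.97-fold lower (−0.98 ± 0.07, adjusted p = 0.00017, 4 of 4 pairs), with C1qa at −0.93, C1qc at −0.87, the antigen-presenting light chain B2m at −0.95 and H2-T23 at −1.4. The H2 genes are polymorphic paralogs and their values are uncertain. Without 1 library the count was 6 (B6 naive CeA or B6 FC BLA), 8 (B6 FC CeA, S1 naive CeA, S1 FC BLA or S1 FC CeA), 10 (S1 naive BLA) or 12 (B6 naive BLA). Medians in these fits ran from −0.84 to −0.66. In the full fit the list median was −0.74 (camera adjusted p = 1.7e-08; adjusted p = 0.32 with an estimated correlation). Microglial markers had 7 of 10 lower, or 9 when adjusted over the list alone, including Trem2, a microglial lipid receptor (−0.95 ± 0.09, adjusted p = 0.00057), its adaptor Tyrobp (−0.88), Ctss (−0.7) and Cx3cr1 (−0.19). Their median was −0.41 (camera adjusted p = 8.3e-06; adjusted p = 0.19 with an estimated correlation). Their count without 1 library was 5 to 8. Cx3cr1 did not pass without B6 naive CeA (adjusted p = 0.11), B6 FC BLA (0.082), B6 FC CeA (0.1), S1 naive BLA (0.11), S1 naive CeA (0.13) or S1 FC BLA (0.13).

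After extinction C1qa (−0.72), C1qb (−0.73), C1qc (−0.71), B2m (−0.72) and the microglial integrin Itgam (−0.88) passed, with list medians of −0.58 for complement (camera adjusted p = 1.7e-06; adjusted p = 0.75 with an estimated correlation) and −0.42 for microglia (camera adjusted p = 1.3e-05; adjusted p = 0.75 with an estimated correlation). By edgeR the change of the strain gap passed for 0 genes of either list.

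**Figure D2:**
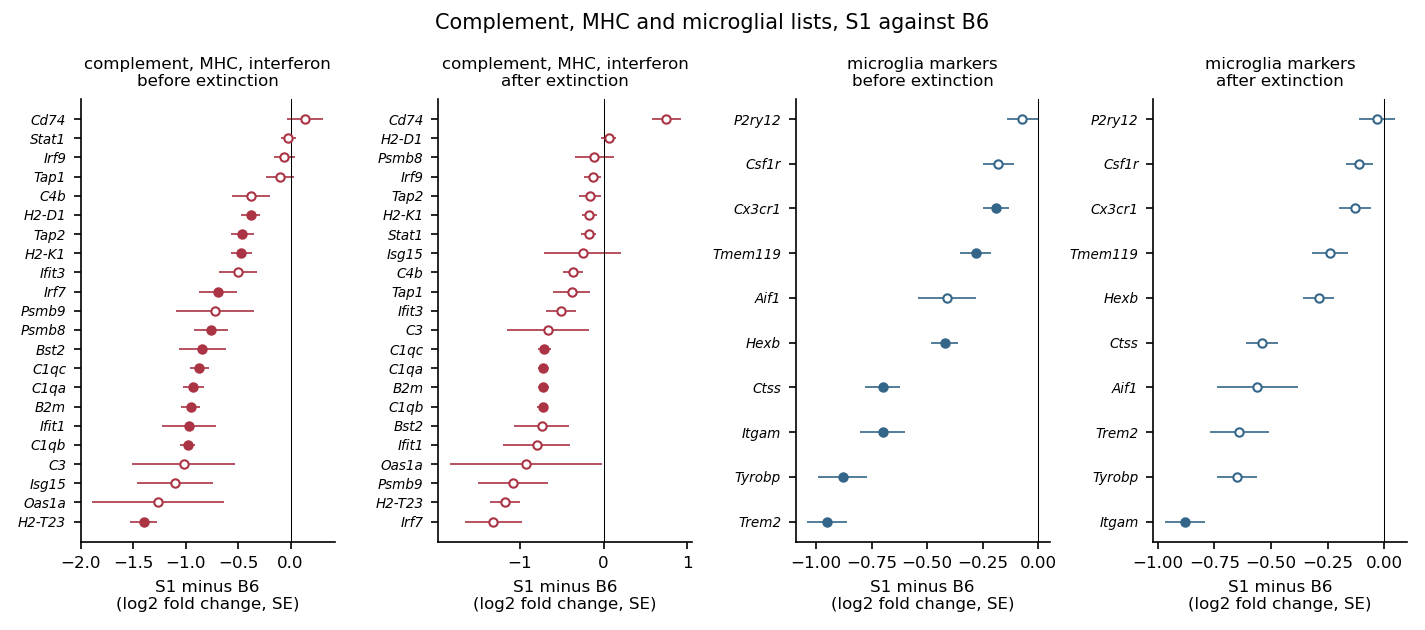
Log2 fold change (S1 minus B6, with SE) of each complement, antigen presentation and interferon gene and each microglial marker, before and after extinction; filled points passed the test. Before extinction 12 of 22 and 7 of 10 genes passed, all of them lower in S1.

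Other glial markers were lower in S1 before extinction as well. Gfap, the astrocyte filament protein, was 3.21-fold lower (−1.68 ± 0.17, adjusted p = 0.00066), and 6 of 10 astrocyte markers were lower, 6 also when adjusted over the list alone (median −0.27, camera adjusted p = 0.005; adjusted p = 0.61 with an estimated correlation). Oligodendrocyte markers had 8 of 10 lower, 9 when adjusted over the list alone, with the myelin genes Mag at −0.71 and Mbp at −0.69 (median −0.52, camera adjusted p = 0.00019; adjusted p = 0.61 with an estimated correlation). Their precursors had 3 of 6 lower, and 3 when adjusted over the list alone (median −0.26, camera adjusted p = 0.3). Endothelial and mural markers had 4 of 10 lower, 5 when adjusted over the list alone, among them the tight junction gene Cldn5 at −0.75 (median −0.2, camera adjusted p = 0.021; adjusted p = 0.61 with an estimated correlation). Blood markers had 2 of 5 lower, 4 when adjusted over the list alone, with the globin gene Hba-a2 at −1.16 (median −1.16, camera adjusted p = 0.021; adjusted p = 0.61 with an estimated correlation). The globin genes of that list have near-identical copies, so its counts and medians between strains are uncertain and need not reflect the amount of blood. Without 1 library the oligodendrocyte count was 3 (S1 naive CeA or S1 FC CeA), 4 (B6 naive CeA or B6 FC CeA), 5 (S1 FC BLA), 6 (B6 naive BLA), 7 (B6 FC BLA) or 8 (S1 naive BLA). Adjusted over the list alone it was 8 to 10. The astrocyte count was 3 without B6 FC CeA, 4 without S1 naive CeA or S1 FC BLA and 5 or 6 without the others. Precursors had 0 lower without B6 naive CeA, B6 FC CeA or S1 naive CeA and 1 without B6 naive BLA or S1 FC BLA. Endothelial and mural markers had 2 without S1 naive CeA or S1 FC BLA. Blood markers had 1 without B6 FC BLA, B6 FC CeA or S1 FC BLA and 4 without B6 naive BLA or S1 naive BLA, with medians of −2.09 without B6 naive CeA, −2.06 without S1 FC BLA and −1.03 to −1.35 without the others. After extinction, where 1.64% of all genes passed, Gfap was −1.36 (adjusted p = 0.013), and no oligodendrocyte marker passed by edgeR (median −0.22, camera adjusted p = 0.13). The regions then went opposite ways. The mean log2 level of oligodendrocyte markers was 0.519 in S1 BLA against 0.335 in B6 BLA, and −0.38 in S1 CeA against 0.157 in B6 CeA.

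Neuropeptide and receptor genes went both ways. Crh, the stress peptide, was −0.74 and the kappa opioid receptor gene Oprk1 −0.75, while the mu opioid receptor gene Oprm1 was 1.61 and the dopamine receptor gene Drd3 1.51. Of 27 neuropeptide genes 3 were higher and 5 lower, or 4 and 5 when adjusted over the list alone, and of 18 monoamine receptor genes 3 were higher and 2 lower on both counts. Among interneuron markers, Htr3a, an ionotropic serotonin receptor (−1.45 ± 0.22), Vip (−0.79) and Npy (−0.42) were lower, 3 of 11 on both counts. Glucocorticoid-responsive genes had 6 of 14 higher and 2 lower, or 8 and 3 when adjusted over the list alone, led by the lipid droplet gene Plin4 (2.75 ± 0.3). Without 1 library the higher glucocorticoid-responsive genes were 1 (B6 FC BLA or B6 FC CeA), 3 (S1 FC BLA or S1 FC CeA), 4 (B6 naive CeA), 5 (S1 naive BLA or S1 naive CeA) or 7 (B6 naive BLA). The lower interneuron markers were 1 in all fits but those without B6 naive CeA (2), S1 naive BLA (2) and B6 naive BLA (4). Neuropeptide counts fell to 1 lower without B6 FC BLA or B6 FC CeA, 2 without S1 FC BLA or S1 FC CeA and 3 without B6 naive CeA, S1 naive BLA or S1 naive CeA. None was higher without B6 naive CeA. Monoamine receptor genes had 0 higher without B6 FC BLA or B6 FC CeA, 1 without S1 FC CeA and 5 without B6 naive BLA. Of the genes named, Crh did not pass without B6 FC BLA (adjusted p = 0.05) or B6 FC CeA (0.055). Oprm1, Drd3, Oprk1, Vip and Npy each failed in 4 to 6 of the 8 fits, while Htr3a and Plin4 passed in all.

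Strain differences were largely shared by the extinction libraries. Pttg1 was −6.07 ± 0.17 there, Rec8 −6.16 ± 0.26, Sugct −5.09 ± 0.35, Myo7a −4.83 ± 0.18, Bub1b −4.76 ± 0.6, Oscar −4.01 ± 0.3 and Tnni1, a slow skeletal troponin, −4.47 ± 0.35. Gdpd3 was 4.63 ± 0.18, Sla2 4.46 ± 0.52, AA465934 4.02 ± 0.21, Prss41 3.78 ± 0.44, the axonemal dynein gene Dnah6 3.66 ± 0.44 and Serpina3n, a protease inhibitor of reactive astrocytes, 3.2 ± 0.13. Klk1b22 was at least 91.3-fold higher and Olfr287 at least 90.2-fold lower, and neither passed with DESeq2 (adjusted p = 0.26 for both). Read assignment is uncertain for these 2, Mir686 (7.08), Arhgap33os (5.96), D4Ertd617e (−6.81), Vmn2r29 (−4.31) and Pou2f1 (6.66), whose CPM ranged from 0.732 to 36.6 in the earlier libraries.

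Of 15996 genes tested after extinction, 262 passed, 102 higher and 160 lower in S1, and DESeq2 called 600. Of these, 243 were also called before extinction, all with the same sign, against 12.9 higher and 16.9 lower for independent lists (91 and 152 observed). Of the 3675 genes called before extinction and tested in both tables, 3379 (91.95%) kept their sign, with a Spearman correlation of 0.883 across genes, which are not independent replicates. Over all 15864 genes in both tables, the same sign held for 71.52%, with a correlation of 0.601. A loss of S1 reads against the reference, not measured here, would be shared by both tables.

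**Figure D3:**
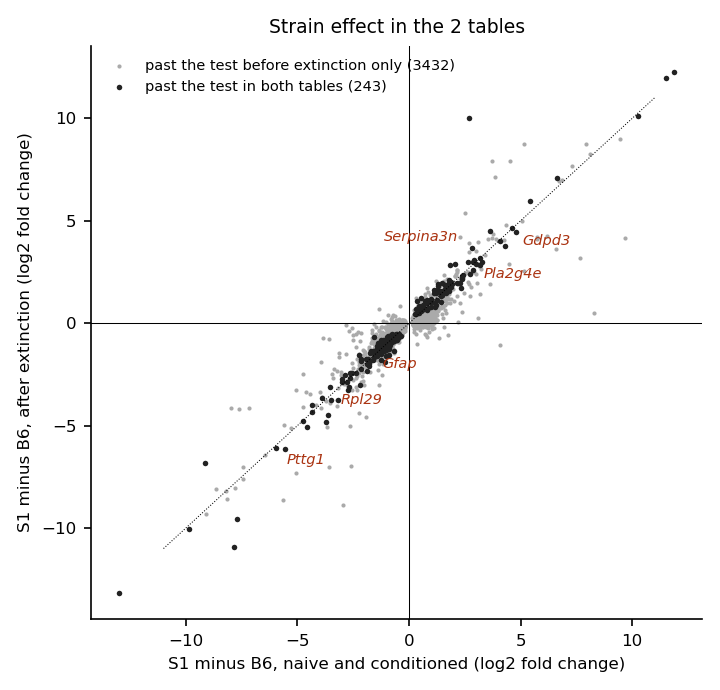
Log2 fold change between strains in naive and conditioned libraries (horizontal) against extinction libraries (vertical) for the 3675 genes called before extinction; each point is a gene, black where it passed in both tables (243). The dotted line marks equal values.

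No gene's strain gap passed for a change with extinction. Across 12 libraries edgeR called 0 of 16523 genes (641 at an unadjusted p under 0.05; smallest adjusted p 0.45), and DESeq2 called 9. The smallest p-values belonged to Tmem87a (0.76 ± 0.1), the collagen chaperone gene Serpinh1 (1.05 ± 0.15) and the globin gene Hbb-b2 (1.51 ± 0.24, uncertain between paralogs) for a gap moved toward S1, and to the chaperone gene Dnajb6 (−0.95 ± 0.14), Tmem245 (−1.62 ± 0.28) and the predicted gene Gm15446 (−1.18 ± 0.22) for the opposite. GABA transmission genes had 23 of 27 negative values (median −0.09, camera adjusted p = 0.026; adjusted p = 0.62 with an estimated correlation), with 0 past adjusted over the list alone. The gap's change ran with transcript length (Spearman correlation across genes −0.415), and the list median was −0.04 once that trend was removed. It was −0.03 without B6 Ext CeA, −0.04 without B6 naive CeA or S1 Ext BLA, −0.15 without B6 naive BLA, −0.17 without B6 Ext BLA and −0.18 without S1 Ext CeA. Leaving out 1 library gave 8 genes without B6 Ext BLA, 6 without B6 Ext CeA, 5 without B6 naive BLA, 5 without S1 Ext CeA, 2 without B6 naive CeA and 0 without each of the others.

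Conditioned mice had higher values of immediate early genes, which mark recent neuronal activity. Of 21 tested, 18 were above naive, with a median of 0.25 (camera adjusted p = 2.4e-17; adjusted p = 0.048 with an estimated correlation; fry adjusted p = 0.04). Over all genes 0 passed by edgeR, and 12 rose when adjusted over the list alone, including Arc, a synaptic plasticity gene (0.57 ± 0.08, adjusted p = 0.002 over the list alone), Fosb (0.55, adjusted p = 0.004 over the list alone) and Fos (0.69 ± 0.18, adjusted p = 0.017 over the list alone). Each of these 3 was higher in 4 of 4 matched pairs. Without 1 library the list-alone count was 4 (B6 FC BLA, where Fos had an adjusted p of 0.071), 7 (S1 FC BLA), 8 (B6 FC CeA) and 9 to 11 for the others. List medians in these fits were 0.23 to 0.27. Naive to conditioned, Arc went from 41.2 to 66.1 CPM in B6 BLA, 30.6 to 51 in B6 CeA, 41.1 to 51 in S1 BLA and 30.1 to 44.4 in S1 CeA.

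Of 14 glucocorticoid-responsive genes 13 were above naive after conditioning, with a median of 0.16 (camera adjusted p = 4.1e-16; adjusted p = 0.048 with an estimated correlation; fry adjusted p = 0.08). Adjusted over the list alone, 5 rose, Plin4 (1.85 ± 0.3), Tsc22d3, a glucocorticoid-induced leucine zipper (0.43 ± 0.07), the sulfotransferase gene Sult1a1 (0.81), Cdkn1a (0.49) and Fkbp5, a regulator of the glucocorticoid receptor (0.33), against 0 over all genes. Without S1 FC BLA 3 rose (Fkbp5 at adjusted p = 0.06) and 4 to 6 without the others. Cdkn1a did not pass without B6 naive BLA (0.068), B6 FC BLA (0.089), S1 naive BLA (0.067), S1 naive CeA (0.093), S1 FC BLA (0.062) or S1 FC CeA (0.07). Of 5 blood markers 0 passed over all genes, and 2 rose when adjusted over the list alone, Hba-a2 at 0.78 (adjusted p = 0.0045) and Alas2, a heme synthesis enzyme, at 1.31 (adjusted p = 0.012). The blood median was 0.78 (camera adjusted p = 0.0029; adjusted p = 0.42 with an estimated correlation), or 0.46 without B6 naive CeA. Without B6 FC CeA 1 rose, Hba-a2, and without S1 naive BLA or S1 FC CeA 3 rose. Other globin genes went both ways in S1 after conditioning. Hba-a1 was at −0.08 in BLA and −4.78 in CeA, and Hbb-bs at −10.41 in BLA. In the same BLA pair Hbb-bt was at 8.69 and Hbb-b1 at 8.85. These values are uncertain because of near-identical copies. GABA transmission genes had 0 past on either count (median −0.01, camera adjusted p = 0.61).

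Ependymal and choroid plexus markers moved further with conditioning than either list, with a median of 1.01 (camera adjusted p = 5.8e-07; adjusted p = 0.21 with an estimated correlation), 2 of 9 past when adjusted over the list alone and 0 over all genes. The largest rises lay in CeA, where Ttr, a choroid plexus transport protein, changed by 1.44 in B6 and 7.16 in S1, against −0.51 and −3.03 in BLA. Not every member followed. Kl changed by 0.95 in B6 BLA and 0.35 in S1 BLA against 0.2 and −0.04 in CeA, and Clic6 by −0.27 to 0.18. Tmem212 and Ccdc153 rose by 2.63 and 1.51 in B6 CeA and by 6.15 and 6.84 in S1 CeA. With 1 library left out the list-alone count was 3 (B6 naive BLA), 2 (S1 FC BLA) or 0 (each other), and the median was 0.44 without S1 FC CeA and 0.6 without S1 naive CeA.

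**Figure D4:**
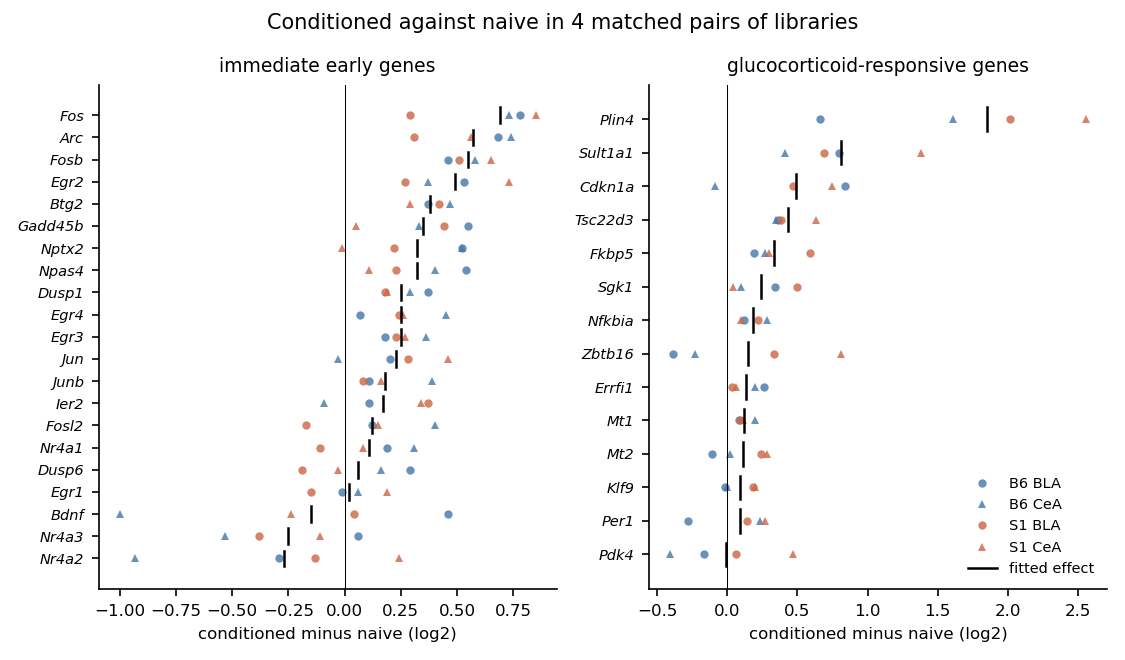
Conditioned minus naive log2 level of each immediate early and glucocorticoid-responsive gene in the 4 matched pairs of libraries (circles BLA, triangles CeA; blue B6, orange S1), with the fitted effect as a black bar. Fitted effects are above 0 in 18 of 21 and 13 of 14 genes.

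For conditioning edgeR called 0 of 16274 genes (571 at an unadjusted p under 0.05), with the connexin gene Gjb6 (0.5 ± 0.07), Arc and Fam107a (0.42 ± 0.06) at the smallest adjusted p of 0.56, and Fut9 (−0.3 ± 0.06), Lypla1 (−0.33) and the microglial receptor gene P2ry12 (−0.32) as the smallest on the lower side. DESeq2 called 21, 16 higher and 5 lower, and 1 gene passed by edgeR without S1 naive CeA or without S1 FC BLA. For a conditioning response that differed between strains edgeR called 0 (293 at an unadjusted p under 0.05) and DESeq2 9, and the smallest p-values belonged to Ube2m (0.84 ± 0.14), Lzts3 (−1.57 ± 0.2), Ube2w (−1.91 ± 0.33), Gvin1, Phf11c and the pseudogene Tmem181c-ps, the last 3 uncertain between near-identical copies. The immediate early list had an interaction median of −0.07 (camera adjusted p = 0.089), with Arc at 0.68 and 0.74 in B6 against 0.31 and 0.56 in S1 (BLA and CeA). BLA excitatory markers had a median of 1.15 in this interaction (camera adjusted p = 7.9e-11; adjusted p = 0.52 with an estimated correlation), and among the CeA libraries their mean log2 level was −0.628 in naive B6, −2.148 in conditioned B6, −2.842 in naive S1 and −1.575 in conditioned S1. That interaction median was 0.37 without B6 naive CeA, 0.52 without S1 naive CeA, 2.07 without B6 naive BLA and 2.19 without S1 naive BLA. Adjusted over the list alone, 12 of these markers passed without B6 naive BLA, 8 without S1 naive BLA and 0 otherwise. Without 1 library the interaction count was 10 (B6 naive BLA), 4 (B6 FC CeA), 3 (S1 FC BLA) or 1 (B6 FC BLA, S1 naive BLA, S1 naive CeA).

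The regions differed in neuron type markers. All 15 BLA excitatory markers were higher in BLA, on both counts (median 4.43, camera adjusted p = 7.9e-14; adjusted p = 0.27 with an estimated correlation), including Slc17a7, a vesicular glutamate transporter (4.66 ± 0.67), and the transcription factor genes Tbr1 (4.81 ± 0.55), Neurod1 (4.74 ± 0.42) and Neurod6 (4.63 ± 0.6). All 18 CeA markers were lower in BLA, on both counts (median −3.23, camera adjusted p = 1.1e-65; adjusted p = 0.035 with an estimated correlation), including the kinase Prkcd (−4.66 ± 0.12), the peptides Pdyn (−4.69), Crh (−4.23), Tac2 (−3.99), Penk (−3.7) and Nts (−3.59), and Gad2 (−1.76 ± 0.05). Slc17a7 was 1750 to 2000 CPM in BLA and 16.4 to 169 CPM in CeA, with the highest CeA value in naive B6.

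The largest values in BLA also included Tfap2d (4.94 ± 0.43), the proton channel gene Otop2 (4.91), Ly6g6e (4.8), Hkdc1 (4.7), Itgbl1 (4.68) and the Wnt agonist Rspo2 (4.56). On the CeA side stood the transcription factor Isl1 (−6.08 ± 0.26), the vesicular monoamine transporter Slc18a2 (−6.07), the vitamin D receptor Vdr (−6.02), Alox12e (−6.01), the calcium-binding protein Scgn (−5.83), galanin (Gal, −5.67), the receptors Brs3 (−5.53) and Sstr5 (−4.94), Nup62cl (−5.18) and Pgr15l (−4.76). Striatal markers had 10 of 12 lower in BLA, 11 when adjusted over the list alone (median −2.48, camera adjusted p = 2.2e-16; adjusted p = 0.25 with an estimated correlation), such as Adora2a (−3.62) and Drd2 (−3.52). Immediate early genes had 11 of 21 higher in BLA and 4 lower, or 12 and 5 when adjusted over the list alone, with Bdnf at 4.38 and Nr4a2 at 3.72 (median 0.37, camera adjusted p = 5.9e-05; adjusted p = 0.23 with an estimated correlation). Bdnf is also on the list of BLA excitatory markers, and whether the regional gap reflects activity was not tested.

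GABA transmission genes split, 8 of 27 higher in BLA (such as Gabra3, 1.65) and 11 lower (Gabrg1 −2.03, Gabrq −2.42), or 9 and 11 when adjusted over the list alone. Endocannabinoid and eicosanoid genes had 11 of 26 higher and 3 lower on both counts, with the cannabinoid receptor Cnr1 at 1.15, the anandamide hydrolase Faah at 1.56 and the cyclooxygenase Ptgs2 at 2.95 (median 0.23, camera adjusted p = 0.0078; adjusted p = 0.3 with an estimated correlation). Glutamate transmission genes had 16 of 30 higher and 5 lower on both counts, with Grm2 at 3.32 (median 0.34, camera adjusted p = 0.0093; adjusted p = 0.63 with an estimated correlation). In all, 7587 of 16274 genes passed, 3778 higher and 3809 lower in BLA, and 49.8% of calls were higher against 34.5% with limma on log2(FPKM + 1), where the median of all genes lay at −0.1 (−0.116 with log2(FPKM + 0.1)).

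**Figure D5:**
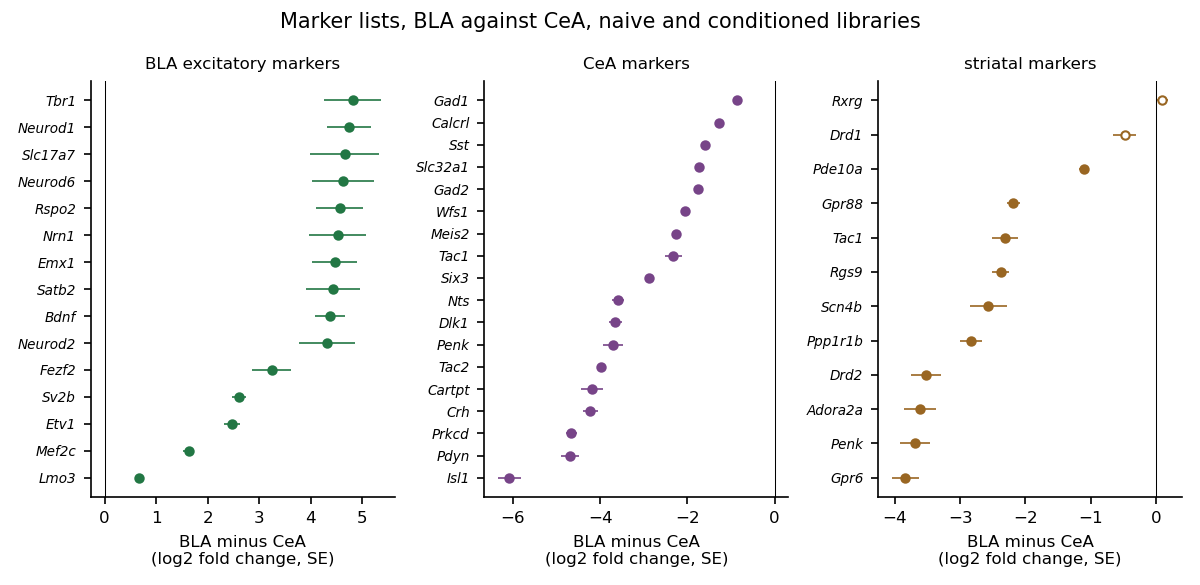
Log2 fold change (BLA minus CeA, with SE) of each BLA excitatory, CeA and striatal marker in naive and conditioned libraries; filled points passed the test. All 15 BLA markers lie above 0 and all 18 CeA markers below.

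After extinction 5804 of 15996 genes differed between regions, 3008 higher and 2796 lower in BLA (38.8% higher with limma on log2(FPKM + 1), against 51.8%). All 15 BLA and 18 CeA markers passed again on both counts, with medians of 5.82 (camera adjusted p = 3.7e-64) and −2.69 (camera adjusted p = 2.1e-40), each at adjusted p = 0.64 with an estimated correlation. Neurod1 was at 0 in CeA and at least 94.1-fold higher in BLA, and setting it to that bound left the median at 5.82. Emx1 was 7.02 ± 0.22, Tfap2d 6.83, Neurod6 6.82, Tbr1 6.68 ± 0.09, Slc17a7 6.61 ± 0.39, Nrn1 6.58 and Itgbl1 6.57. Lower in BLA were Vdr (−6.52), Pgr15l (−6.17), Nup62cl (−5.98), Isl1 (−5.72), the growth factor Fgf3 (−5.54), Slc18a2 (−5.54), Gal (−4.98), Irs4 (−4.9) and Prlhr (−4.65). Hist2h2aa2 (8.25), Hbb-bs (8.24) and Hbb-b1 (−8.14) have near-identical copies, and their values are uncertain.

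A strain gap that differed between BLA and CeA passed for 5 genes, 1 with the gap higher in BLA and 4 with it lower (1404 at an unadjusted p under 0.05; DESeq2 called 120, including all 5). Ankrd33b had 106 and 108 CPM in B6 BLA but 10.2 and 13.3 CPM in S1 BLA, while CeA had 25 to 34.6 CPM in both strains. Col6a5, a collagen chain, had 41.7 and 47.7 CPM in S1 CeA against 3.64 and 4.58 CPM in B6 CeA. Ankrd33b passed without any 1 library. Col6a5 did not pass without B6 naive CeA (adjusted p = 0.15), S1 naive BLA (0.16), S1 naive CeA (0.056), S1 FC BLA (0.12) or S1 FC CeA (0.11). Leaving out 1 library gave 13 genes without B6 FC CeA, 12 without B6 naive BLA, 3 without B6 naive CeA, 3 without S1 FC BLA, 3 without S1 FC CeA and 1, Ankrd33b, without S1 naive BLA.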

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

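Chosen after the results were seen were the tests of fewer glial cells and fewer microglia, with the lists of other neuronal and other microglial genes they use, the test of blood in the conditioned tissue, the counts of distinct and within-pair splits, the removal of the length trend, and the fits of each region alone.

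Strain gaps that differed between BLA and CeA by the interaction test set 5 genes apart. The gap in BLA minus the gap in CeA was −2.87 ± 0.19 in Ankrd33b (adjusted p = 0.014), where S1 BLA stood below the other libraries, also after extinction (11.4 CPM against 94.8 CPM in B6 BLA). It was −3.41 ± 0.3 in Col6a5 (adjusted p = 0.04), high in S1 CeA and again after extinction at 31.2 CPM. In Nabp1 it was 1.75 ± 0.16 (adjusted p = 0.04), with 18.2 and 19.4 CPM in S1 BLA, but after extinction B6 BLA was the high library at 20 CPM and S1 BLA had 7.62 CPM. Coch, an extracellular protein of the inner ear, had −1.73 ± 0.16 (adjusted p = 0.04), with 9.81 and 11.4 CPM in S1 BLA, and 10.9 CPM there after extinction. Slc24a2, a sodium and calcium exchanger, had −1.56 ± 0.15 (adjusted p = 0.04), with 393 and 429 CPM in B6 BLA against 134 and 149 CPM in S1 BLA. After extinction Slc24a2 had the wider strain gap in CeA, with 106 CPM in B6 and 31.4 CPM in S1 against 330 and 236 CPM in BLA, so the order of the regions turned. Ankrd33b passed without any 1 library. Col6a5 passed without B6 naive BLA, B6 FC BLA or B6 FC CeA, Slc24a2 without B6 naive CeA or B6 FC CeA, Coch without B6 naive BLA and Nabp1 without B6 FC CeA. Without each other library their adjusted p ran from 0.056 (Col6a5) to 0.19 (Coch, Nabp1 and Slc24a2).

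GABA and glutamate transmission genes had list medians of 0.11 and 0.23 between strains before extinction, toward S1. With the length trend removed the medians were 0.03 (95% interval −0.02 to 0.13) and 0.09 (0.01 to 0.19), under the 0.055 and 0.114 that mark a fraction 0.5 of the first values, although both intervals reach above them. A trend on transcript length may therefore account for most of the shift, but the removal cannot settle it. The trend was not constant across libraries. Between strains its Spearman correlation was 0.401 before extinction and 0.108 after it. The interactions of strain with region and with conditioning gave −0.324 and 0.248. The lists had long transcripts (medians of 4066 and 4448.5 bases), and the trend was fitted over all genes. A shift of long neuronal transcripts as a class would be removed with it. Single genes such as Gabra2 (0.36) and Gabrb1 (0.69) stayed higher after the removal. The counts also rest on single libraries, as 0 GABA genes were higher without B6 naive CeA or S1 naive CeA and 0 glutamate genes without B6 FC CeA. Whether the S1 tissue held fewer glial cells cannot be told apart, since 24 other neuronal genes had a median of 0.04 (−0.06 to 0.13), on both sides of the bound of 0.055. A difference in transmission genes between the strains themselves stays open and untested.

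Complement, antigen presentation and microglial genes were lower in S1, by medians of −0.74 and −0.41. Whether fewer microglia in the S1 tissue account for the microglial part cannot be told apart. The 25 other microglial genes had a median of −0.31 (−0.41 to −0.19), with 13 of them lower in S1. That median lay past the −0.206 that is 0.5 of the list's fall, but the interval holds this bound. For the complement list fewer microglia cannot be told apart, as the interval of those genes holds the bound of −0.371. Their median lay above 0.5 of the fall in the C1q genes, Trem2 and Tyrobp (median −0.93, bound −0.464) by 0.06 to 0.27. Those 5 are among the deepest falls of the pattern, so that comparison excludes nothing. The length trend as the whole cause is argued against, as its removal left medians of −0.6 (−0.75 to −0.42) and −0.28 (−0.67 to −0.2), which exceeded 0.5 of their first size by 0.15 to 0.29 and by 0.01 to 0.31. Reads of polymorphic H2 paralogs lost against the reference were not analysed here and stay open for those genes. A lower expression per microglial cell in S1 stays open as well and was not tested.

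Immediate early and glucocorticoid-responsive genes had medians of 0.25 and 0.16 after conditioning. The length trend was small for conditioning (Spearman 0.092; medians of −0.022 in the shortest and 0.013 in the longest transcripts), and a trend of that size argues against length as the source. Its removal, which could move little, left 0.25 (0.11 to 0.32) and 0.17 (0.13 to 0.41), above 0.5 of the first values by 0.05 to 0.16 and by 0.07 to 0.21. Of 33 splits of the 8 libraries (29 distinct fits), 1, the real one, had an immediate early median as far from 0 as 0.249 (highest other 0.232). The 8 splits that only swap labels within matched pairs (highest other 0.157) are too few for a share under 0.05. Chance cannot be excluded for the glucocorticoid median of 0.161, which 11 of 33 splits reached (highest other 0.213). More blood in the conditioned tissue cannot be told apart as a source, because the immediate early list's strain median of −0.07 (−0.15 to 0.02) lay above the bound of −0.187 by −0.02 to 0.23. That bound rests on Hba-a2 alone. Other globin genes went both ways in S1 BLA after conditioning, with Hba-a1 at −0.08, Hbb-bs at −10.41, Hbb-bt at 8.69 and Hbb-b1 at 8.85. Ependymal and choroid plexus markers had a median of 1.01, or 0.44 to 1.21 with 1 library left out. In those fits 0 of them passed over all genes and 0 to 3 over the list alone. A difference in the dissected tissue stays open and was not tested. A response to conditioning itself, or to handling and shock as such, may underlie the values and stays untested.

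For counts of genes, 1 of 33 splits called as many as 3712 for strain (highest other 0), and 1 of 33 as many as 7587 for region (highest other 1). The other splits were fitted without the real factor, whose effect then widened their residual spread. Their low counts therefore cannot exclude chance. The 8 splits within matched pairs are too few for a share under 0.05 here too. For conditioning the splits say nothing on chance, since a real count of 0 is reached by 33 of 33 whatever the data (highest other 10).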

How the results depend on the processing

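Removal of the length trend and fits of each region alone were chosen after the results were seen. Of 281 gene values past the threshold, 0 reversed in the fits run for them by DESeq2, with relative log expression factors or, for 170 of them, with 1 library left out. Of those 170, 53 no longer passed in some leave-one-out fit, and of the 281, 12 no longer passed with DESeq2 and 1 with relative log expression factors. Of 35 named as not past, 18 passed with DESeq2. Counts stayed within 1.5 times of the reported value under every setting not named here, and the causes of the changes below were not tested unless stated.

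For strain before extinction, leaving out 1 library gave 1489 to 5227 genes (least shared with the reported calls 1467). The BLA libraries alone gave 1305 (1130 shared). The fit of the CeA libraries alone held as many libraries and is not among the settings that moved. Fewer libraries in the fit therefore cannot by itself account for the lower BLA count. For strain after extinction DESeq2 called 600 (254 shared), the CPM filter 425 (261 shared), limma 463 (245 shared) on log2(FPKM + 1) and 426 (247 shared) on log2(FPKM + 0.1), and no filter 161 (161 shared), where more genes were tested. Leaving out a library after extinction left no residual degrees of freedom, so no value exists. For region before extinction leave-one-out counts ran from 6206 to 7666.

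For conditioning, against 0, DESeq2 called 21, summed BLA and CeA counts 44, the BLA libraries alone 13 and the CeA libraries alone 6. Leaving out 1 library gave 0 to 1 gene, Gopc without S1 naive CeA and Nutf2-ps1 without S1 FC BLA, both chosen after their values were seen. For strain by conditioning DESeq2 called 9, limma 1 on log2(FPKM + 1) and 1 on log2(FPKM + 0.1), in both cases Tmem181c-ps, and leave-one-out fits 0 to 10. For strain by region DESeq2 called 120, no filter 1, limma 8 on log2(FPKM + 1) and 0 on log2(FPKM + 0.1), and leave-one-out fits 1 to 13. For the change of the strain gap with extinction DESeq2 called 9 and leave-one-out fits 0 to 8.

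The share of genes that kept their strain sign in the extinction table was 91.95% among called genes, 71.52% over all genes, 97.72% among genes called at 0.01, and 90.39% among DESeq2's calls. Of 191 list tests, 81 passed with the preset correlation, 3 with an estimated correlation and 22 with fry (19 shared). The medians of the GABA list (0.11) and the glutamate list (0.23) moved to 0.03 and 0.09 without the length trend, and the GABA median to 0.06 in BLA alone. Without that trend the immediate early strain median also went from −0.07 to −0.04 and that of extracellular matrix genes from −0.13 to −0.27. With limma on log2(FPKM + 1) medians moved by over 1.5 times for strain in the complement list (−0.74 to −0.39, and −0.58 to −0.26 after extinction) and the GABA list (0.11 to 0.07). Small strain medians moved as much, in the phospholipase A2 (−0.06 to −0.01, and −0.08 to −0.04 after extinction), eicosanoid (−0.06 to −0.1), CeA (0.1 to 0.05), striatal (−0.02 to −0.07) and ependymal lists (−0.04 to −0.19). For region they moved in the BLA (4.43 to 2.94, and 5.82 to 3.48 after extinction), immediate early (0.37 to 0.24), eicosanoid (0.23 to 0.04) and ependymal lists (−3.09 to −1.06). For conditioning the ependymal median went from 1.01 to 0.53 and the blood median from 0.78 to 0.49, and for strain by conditioning the BLA median from 1.15 to 0.49.

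The block for matched pairs gave 3631 genes for strain (3397 shared), 7090 for region and 0 for conditioning, and was run for these comparisons alone. BLA and CeA libraries of a strain and condition may share mice, which the labels do not say. Only the block for region pairs such libraries. The blocks for strain and conditioning pair other libraries, so they do not check for shared mice. In simulated data 2-fold changes were recovered in 38% of genes for strain by conditioning and 58% for strain by region and for the change of the gap, so changes of that size may have been missed there. With 1 library per group, differences between single mice were not measured.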

Other observations

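The removal of the length trend was chosen after the results were seen, and the other tests were not. Ribosomal protein genes, which are short (median transcript 734 bases), had 32 of 78 lower in S1 before extinction and 0 higher, or 52 lower when adjusted over the list alone, with a median of −0.24 (camera adjusted p = 1.1e-13; adjusted p = 0.61 with an estimated correlation). Without 1 library the count was 12 (B6 FC BLA), 13 (B6 naive CeA), 15 (B6 FC CeA or S1 naive CeA), 19 (S1 naive BLA), 22 (S1 FC CeA), 25 (S1 FC BLA) or 71 (B6 naive BLA). Adjusted over the list alone it was 22 to 73 (lowest without B6 FC BLA, highest without B6 naive BLA). Without the length trend the median was −0.02. Rpl29 was −3.53 ± 0.11 and Rps3a1 −1.59, both uncertain because of processed copies. The respiratory chain list had 3 of 15 lower, 2 when adjusted over the list alone, with Cox6c at −0.56 (median −0.22, camera adjusted p = 0.029; adjusted p = 0.75 with an estimated correlation), and a median of −0.01 without the length trend. Without B6 naive BLA 10 were lower (13 over the list alone), without S1 naive BLA or S1 FC BLA 2, and without each other library 1. Between regions 63 of 78 ribosomal protein genes were lower in BLA and 1 higher, or 70 and 1 when adjusted over the list alone (median −0.42, camera adjusted p = 4.7e-09; adjusted p = 0.65 with an estimated correlation).

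Oligodendrocyte markers had 10 of 10 higher in BLA before extinction, with Mbp at 0.7 and Mobp at 0.74 (median 0.62, camera adjusted p = 0.014; adjusted p = 0.65 with an estimated correlation). Their strain gap was smaller in BLA than in CeA, with an interaction median of 0.55 (camera adjusted p = 1.7e-10; adjusted p = 0.4 with an estimated correlation) and 5 of 10 genes past when adjusted over the list alone, against 0 over all genes. Without 1 library 3 (B6 FC CeA) to 8 (B6 naive BLA or B6 naive CeA) passed over the list alone, with medians of 0.42 to 0.7. Striatal markers had an interaction median of 0.64 (camera adjusted p = 1.3e-08; adjusted p = 0.4 with an estimated correlation) and 5 past when adjusted over the list alone, against 0 over all genes. Their strain gap turned sign between the regions. The mean log2 level in BLA was −1.341 and −0.994 in S1 against −1.415 and −1.459 in B6 (naive and FC), and in CeA 1.118 and 0.68 in S1 against 1.274 and 1.204 in B6. Those 5 became 0 without B6 naive CeA, B6 FC CeA, S1 FC BLA or S1 FC CeA, 3 without B6 naive BLA or B6 FC BLA, 9 without S1 naive BLA and 10 without S1 naive CeA. Their median ran from 0.37 (S1 FC BLA or S1 FC CeA left out) to 0.96 (S1 naive CeA left out). Drd2, the D2 dopamine receptor gene, was 4.18 and 4.36 CPM in B6 BLA against 5.1 and 9.77 CPM in S1 BLA (naive and FC), and 57.2 to 73.9 CPM in CeA. Genes of the interneuron list differed by region, with Cck at 3.8, Vip at 3.37 and Pvalb at 2.57 higher in BLA and Sst at −1.59 and Lamp5 at −1.53 lower. Sst is also on the list of CeA markers, and tissue libraries cannot assign these values to interneurons.

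Ependymal and choroid plexus markers had 5 of 9 lower in BLA, 6 when adjusted over the list alone, with Clic6 at −3.81 and Kl at −3.09 (median −3.09, camera adjusted p = 0.004; adjusted p = 0.38 with an estimated correlation). Folr1 was at 0 in a group in this comparison and in that of conditioning, and its bound left both medians as they were. After extinction the regional median was −0.52 while the mean was 0.09, or −0.54 with Ttr at its bound, and the median was −1.19 with limma on log2(FPKM + 1) and −1.96 on log2(FPKM + 0.1).

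Between strains before extinction, eicosanoid and endocannabinoid genes had 2 of 26 higher and 5 lower, or 2 and 6 when adjusted over the list alone (median −0.06, camera adjusted p = 0.39), with Ptgds at 0.52 and Ltc4s at −1.39. Extracellular matrix genes had 1 of 14 higher and 3 lower, or 1 and 5 when adjusted over the list alone (median −0.13, camera adjusted p = 0.29), and a median of −0.27 without the length trend, with Tnr at 0.99 and Adamts4 at −1.36. Immediate early genes had 0 higher and 1 lower, Ier2 at −0.53, or 0 when adjusted over the list alone (median −0.07, camera adjusted p = 0.58). CeA markers had 3 of 18 higher and 1 lower on both counts (median 0.1, camera adjusted p = 0.61), and 1 of 5 intercalated cell markers was higher on both counts (median 0.06, −0.01 by limma on log2(FPKM + 1)). BLA excitatory (median −0.31), striatal (−0.02) and ependymal markers (−0.04) had 0 past on either count, with camera adjusted p of 0.39, 0.98 and 0.58. Medians of eicosanoid and endocannabinoid genes ran from −0.14 without S1 FC BLA to −0.01 without S1 FC CeA. The BLA excitatory median was −0.01 without B6 naive CeA and −0.08 without S1 naive CeA. The ependymal median ran from −1.06 without S1 FC CeA, where 2 markers were lower, to 0.01 without B6 naive BLA, and was −0.65 with limma on log2(FPKM + 0.1). The striatal median ran from −0.11 without B6 naive BLA to 0.13 without S1 FC CeA. Of the sex-linked genes Ddx3y (0.46) and Uty (0.32) were higher, and of the strain reference genes Gabra2 (0.31) was higher and Nnt, a mitochondrial transhydrogenase, lower (−0.53). Leaving out 1 library moved most of these small counts. Higher CeA markers were 0 without B6 naive CeA, B6 FC BLA, S1 naive CeA or S1 FC BLA, 1 without S1 naive BLA or S1 FC CeA and 5 without B6 naive BLA. Lower eicosanoid and endocannabinoid genes were 2 without S1 naive BLA or S1 FC BLA, 4 without S1 FC CeA and 3 without each other library. Ptgds passed only without B6 naive CeA or S1 naive CeA, and Ier2 only without B6 naive BLA or S1 FC BLA. Tnr did not pass without B6 naive CeA (adjusted p = 0.099), B6 FC BLA (0.1), B6 FC CeA (0.13) or S1 naive CeA (0.068), nor Gabra2 or Uty in 5 of the 8 fits each. The intercalated cell marker did not pass without B6 naive CeA, B6 FC CeA, S1 FC BLA or S1 FC CeA.

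Libraries of the extinction table held less of the ribosomal RNA precursor Rn45s, 0.031% to 0.054% of counts, than the naive and conditioned libraries, at 0.154% to 1.706%.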
